A study of Oryza sativa with 8 samples.

How the data were processed

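Small RNA libraries were made from the immature 9th leaf of rice (Oryza sativa, cultivar Nipponbare). Per the labels' protocols, plants grew in 2 growth chambers at 28°C by day and 23°C by night, with 14 h of light, 0.5 g of nitrogen per plant and an ambient CO2 level of 320 to 360 ppm. CO2 was then raised to 1000 ppm at the start of the light period, and leaves were fixed 7 h and 13.5 h later. The 4 groups (ambient and elevated CO2 at each time) held 2 libraries each. Per the series' design text, the 2 libraries of a group came from independent experiments on different plants, so p-values measure the spread between such experiments, as far as 2 libraries show it. The chamber of a library was not a term in any model. A difference between chambers therefore cannot be told apart from a CO2 effect here.

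The authors deposited raw read counts per mature miRNA, with the names of the precursors of each. Per the file headers, the mature miRNAs are those of miRBase. The aligner, the counter and the miRBase release are not given in the sources used here. The count table held 328 rows, and each row had at least 1 read in all 8 libraries, so rows with a count of 0 had been left out before deposit. Reads that match several mature miRNAs were counted at each of them: the 328 rows held 215 distinct sets of counts, and 1 set was repeated in 16 rows. The counts of miR396f-5p lay between 0.4998 and 0.5 times those of miR396e-5p in every library, so these 2 rows shared reads as well. The authors listed the precursors MIR396e and MIR396f for miR396e-5p and only MIR396f for miR396f-5p. A read may thus enter a row once per precursor, so a count can exceed its number of reads. The authors also deposited RPM values. In each library the count divided by the RPM gave 1 total, slightly above the sum of the rows. What the remaining reads of that total were is not given in the sources used here. A further table deposited by the authors held log2 values with nearly the same distribution in every library. Their order within a library was that of the RPM values (Spearman's rho of 1), and the method behind them is not given in the sources used here.

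Differences were tested on the raw counts with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test with robust dispersions, TMM scaling, two-sided). Rows were kept by filterByExpr on the 4 groups with a minimum count of 10 and a minimum total of 15, which left 313 of 328 rows. P-values were adjusted by the Benjamini-Hochberg method over the rows of a comparison, with a threshold of 0.05. The CO2 effect at each time and the difference between these effects came from a model with 1 mean per group, fitted to all 8 libraries so that groups of 2 shared an estimate of the spread. The CO2 effect over both times and the time effect over both CO2 levels came from a model with CO2 and time as additive terms. The same tests were run on family totals, for which the distinct sets of counts of all rows with the same miR number were summed, both arms together. Of 117 families, 109 passed the filter. CPM values are counts scaled by TMM over the total of the deposited rows, in which shared reads are counted repeatedly. Log2 fold changes are given with their standard error (SE), which was taken as the log2 fold change divided by the square root of F, or with a 95% confidence interval from the same SE. These errors cover the spread between libraries. Reads without molecular identifiers are not independent molecules, and no correction for amplification was possible.

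A total of 11 lists of miRNA families was fixed in advance. They were SPL-targeting, AP2-targeting, auxin pathway, leaf development transcription factors, copper, phosphate and sulfate, nitrogen-linked, biogenesis feedback, cereal-restricted, 24-nt long miRNAs, and reproductive phasiRNA triggers as markers of another tissue. Of their 39 families, 33 had a row and 32 passed the filter. The lists were tested on the 201 distinct sets of counts that passed the filter with camera (limma 3.58.1), which compares a list with all other miRNAs, at a preset correlation of 0.01 and again with an estimated correlation. Values of list members come from this fit of distinct sets and differ slightly from those of the fit of all rows. The lists were also tested with fry, which asks whether the members of a list move, on balance, in 1 direction. P-values were adjusted over the 11 lists of a comparison.

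The miRNAs named in the text followed a rule set in advance. For each comparison, up to 12 rising and 12 falling miRNAs past the threshold were named, with rows of identical counts named once. Where fewer than 10 passed, those with the smallest p and a mean of at least 10 CPM were added until 10 were named, as values that did not pass. Up to 4 members of each list with the smallest p served as examples, and the 10 families with the highest share of counts described the libraries. Features outside this rule are named as chosen after their values were seen.

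The comparisons, lists, naming rule and most alternatives were chosen before the data were examined. The alternatives were relative log expression factors or library totals in place of TMM, no filter, a filter at a mean of 10 CPM, DESeq2 1.42.0 (Wald test, no independent filtering), limma on log2(RPM + 1), on log2(RPM + 0.1) and on the authors' normalized log2 values, rows with identical counts kept once, the libraries of 1 time alone, the replicate number as a block, and each library left out in turn. Where a fit left a group with 1 library, that library was assumed to vary like the other groups. For family totals under limma, the RPM values of the distinct rows were summed, and the authors' log2 values were turned back to a linear scale for the sum. Alternatives chosen after seeing the data are named as such in the closing section. Scaling mattered for the direction of small changes. With library totals in place of TMM, the median log2 fold change over the 313 rows moved from 0.036 to −0.48 for CO2 at 7 h, from −0.063 to 0.61 for the difference between times, from 0.027 to −0.17 for CO2 over both times and from 0.020 to −0.43 for time, while at 13.5 h it was 0.078. The share of rows with a higher value then fell from 53.7% to 16.6% for CO2 at 7 h and from 51.1% to 14.7% for time. Directions in the report are relative to the TMM scaling.

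The tests were checked on simulated counts drawn from the row means, the row spreads and the library totals of the real data, with each row drawn separately. For CO2 at 13.5 h with 313 rows, edgeR recovered 14% of the miRNAs changed 2-fold, 65% of those changed 4-fold and 97% of those changed 8-fold. For CO2 over both times the shares were 40%, 94% and 100%. Of the 190 calls at 13.5 h 14 were false, and of the 247 over both times 13 were. A copper list raised 4-fold in elevated CO2 at both times was called by camera in 5 of 5 simulations. Such draws carry neither correlation between miRNAs nor reads shared between rows. The estimated correlation of the real copper members was 0.66 to 0.72 across the comparisons. These simulations therefore cannot check camera at its preset correlation for such members. The recovered shares and false calls of edgeR may likewise be too favourable for the real libraries.

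Totals over the deposited rows ran from 826500 counts in replicate 1 of elevated CO2 at 7 h to 21350528 in replicate 1 of ambient CO2 at 13.5 h, a 25.8-fold range. A count of 1 was worth 1.19 CPM in the shallowest library and at most 0.242 CPM in the others. Genome coordinates were not used here. Precursors are named as in the count table.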

Results

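Mature miRNAs were profiled by small RNA sequencing in the developing 9th leaf of rice after 7 h and 13.5 h under elevated CO2 (1000 ppm) and in leaves kept at ambient CO2. The study asked how the miRNAs of a developing leaf respond to elevated CO2. Each of the 4 groups had 2 libraries. Total counts over the 328 deposited miRNAs were 5790075 and 10269765 for ambient CO2 at 7 h and 826500 and 10732231 for elevated CO2 at 7 h. They were 21350528 and 3929087 for ambient CO2 at 13.5 h and 15353108 and 5571726 for elevated CO2 at 13.5 h.

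The miR166 family, which targets class III HD-ZIP transcription factors that set leaf polarity, held 84.9% ± 3.70 (SD, n = 8 libraries) of the counts when identical sets of counts were summed once. Rows of a family can still share reads, as miR396e-5p and miR396f-5p do, so the shares given here are of counts and not of reads. Its share ran from 79.9% in the shallowest library to 90.2% in replicate 1 of elevated CO2 at 13.5 h. The families next in abundance were miR1425 with 3.24% ± 0.823, miR396 with 2.11% ± 1.69 and miR159 with 1.57% ± 0.757. The miR396 family targets growth-regulating factors and miR159 targets GAMYB-like transcription factors. They were followed by miR5077 with 0.814%, miR1862 with 0.751%, miR171 with 0.650%, miR168 with 0.574%, miR160 with 0.542% and miR167 with 0.519%. Of the reproductive list, only miR2118, a trigger of phased small RNAs in inflorescences, passed the filter, with 0.0291% of counts.

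No pair of replicates looked like copies of 1 library, since their counts differed by more than counting noise in all 4 groups (chi-square per degree of freedom of 91.3 to 528). Their Spearman's rho across miRNAs was 0.907 to 0.972. Among 106 distinct miRNAs with a mean of at least 10 CPM, 6.60% differed by more than 2-fold between the replicates of ambient CO2 at 7 h. The shares were 17.0%, 23.6% and 18.9% in elevated CO2 at 7 h, ambient CO2 at 13.5 h and elevated CO2 at 13.5 h. A total of 3 libraries lay apart on the first principal component, which held 41.5% of the variance. These were replicate 1 of elevated CO2 at 7 h and replicate 1 of both groups at 13.5 h. They also had the highest miR396e-5p, at 7721, 6032 and 5390 CPM, against 594 to 1704 CPM in the other libraries.

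**Figure D1:**
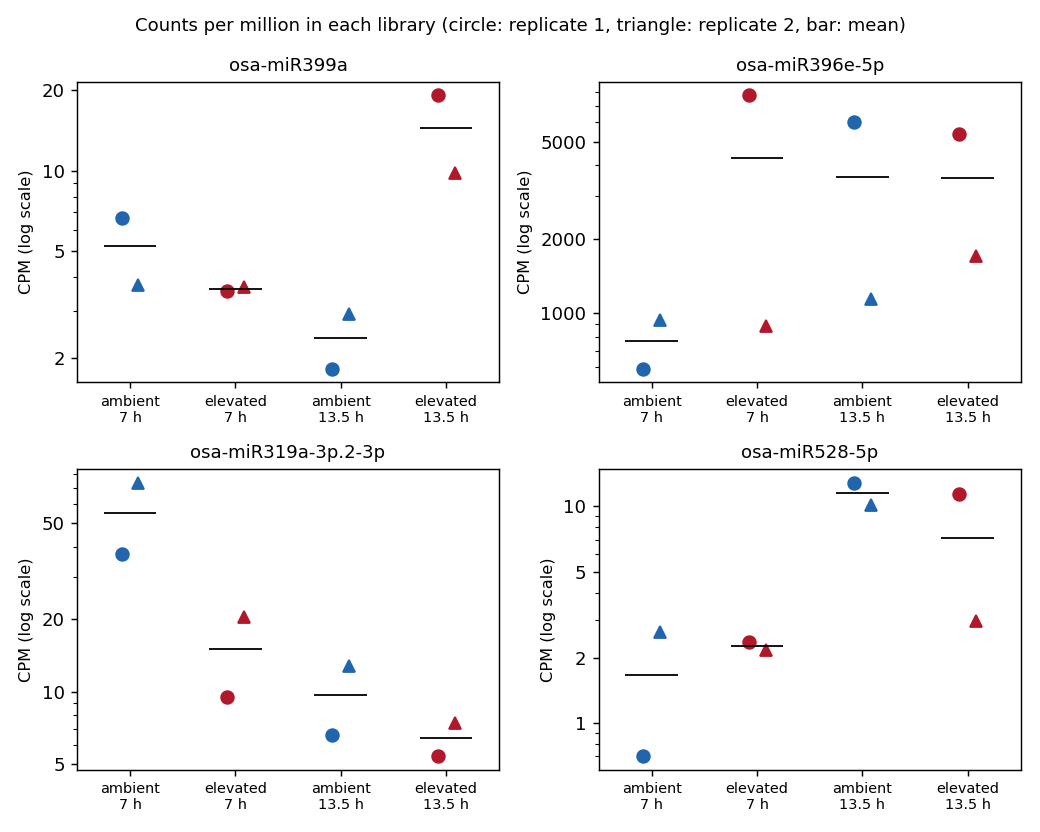
TMM-scaled CPM (log axis) of 4 miRNAs in each of the 8 libraries, with circles for replicate 1, triangles for replicate 2, blue for ambient and red for elevated CO2, and black bars for the mean of the 2 libraries. The counts shared by miR399a, b and c lay at 19.1 and 9.80 CPM in elevated CO2 at 13.5 h, above the 1.82 and 2.91 CPM of ambient CO2, while miR396e-5p differed between replicates by up to 3.12 on the log2 scale.

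After 7 h no mature miRNA and no family passed the test between elevated and ambient CO2 in the fit without a replicate block, and the lowest p-values among well-counted miRNAs belonged to miR319 and miR164. The counts shared by miR319a-3p.2-3p and miR319b, which target TCP transcription factors of leaf growth, were at 9.49 and 20.5 CPM in elevated CO2 against 37.1 and 73.5 CPM in ambient CO2. Their log2 fold change was −1.78 ± 0.56 (SE, adjusted p = 0.834 by edgeR's quasi-likelihood test), with both elevated libraries below both ambient ones. The 9.49 CPM of miR319 rests on few counts, since it came from the shallowest library, where a count of 1 was worth 1.19 CPM. The counts shared by miR164a, b and f, which target NAC transcription factors of organ boundaries, had a log2 fold change of 2.57 ± 0.81. Here replicate 1 of elevated CO2 held 569 CPM and replicate 2 held 76.9 CPM, against 53.6 and 53.9 CPM in ambient CO2. The same replicate 1, the shallowest library, was also far above the others at 7 h in miR168a-3p (2.36 ± 1.21), miR396e-5p (2.49 ± 1.44) and miR396f-5p (2.49 ± 1.44). Without it the value of miR168a-3p was −0.082. Smaller values that did not pass were 0.72 ± 0.37 for miR1876, 0.67 ± 0.39 for miR2877 and 0.81 ± 0.51 for miR812n-3p. They were 0.65 ± 0.42 for miR396c-5p and −0.59 ± 0.42 for miR171i-3p, which targets GRAS-domain regulators.

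The leaf development list held 34 members from 7 families, and members of a family can share reads. Before the filter miR166 had 14 distinct sets of counts and miR396 had 8, so most members come from these families. In the lists at 7 h, 24 of these 34 members lay higher in elevated CO2 and 10 lower, with 0 members past the threshold by edgeR and an adjusted p of 0.0900 by camera. Their median of 0.18 became −0.24 with library totals as the scaling. The nitrogen-linked list holds miR169, which targets NF-YA factors, and miR444, which targets MADS-box factors. Of its 14 members, 10 lay lower, with a median of −0.50 and an adjusted p of 0.0900 by camera. The copper list held 5 members from 3 families, with both arms of miR528 among them. These families, miR397, miR408 and miR528, held a mean of 0.00185%, 0.00560% and 0.00328% of counts. They thus had few counts in the shallowest library. All 5 copper members lay higher with a median of 0.30, which was −0.096 with library totals, and an adjusted p of 0.152 by camera. The 4 biogenesis feedback members come from miR162, which acts against DCL1, and miR168, whose 5p arm acts against AGO1. They include miR168a-3p, the other arm. They had a median of 0.31, which was −0.10 with library totals, a mean of 0.70 and an adjusted p of 0.152 by camera. Both AP2-targeting members and all 3 reproductive members lay lower, with an adjusted p of 0.152 for each list by camera. The SPL-targeting list (adjusted p = 0.762), the auxin list (0.291), the phosphate and sulfate list (0.920), the cereal-restricted list (0.920) and the 24-nt list (0.920) did not pass by camera either. The phosphate and sulfate list had a median of 0.12 against a mean of −0.024 and a test that pointed down. No member of any list passed when adjusted over the list alone. Without replicate 2 of ambient CO2 at 7 h, the leaf development and copper lists passed as higher (adjusted p = 0.0435 and 0.000255 by camera, or an adjusted p of 0.616 for each with an estimated correlation). By fry the nitrogen-linked and reproductive lists passed without replicate 1 (adjusted p = 0.0197 and 0.0377) or 2 (0.0212 and 0.0387) of elevated CO2 at 13.5 h, but with an estimated correlation their adjusted p was 0.667 and 0.671.

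The count of 0 miRNAs by edgeR at 7 h stood beside 7 at an unadjusted p under 0.05, where 15.7 of 313 would come by chance. These 7 rows held 4 distinct sets of counts. DESeq2 called 4, miR164a, b and f and miR817, and limma called 0. For families the counts were 0 by edgeR with 4 at an unadjusted p under 0.05, 2 by DESeq2 (miR164 and miR817) and 0 by limma; miR817 was chosen after its values were seen and rests on 16 reads in the shallowest library. Without replicate 2 of elevated CO2 at 7 h, which leaves 1 elevated library, edgeR called 5 miRNAs (miR164a, b and f, miR168a-3p and miR817) and 2 families (miR164 and miR817). With the replicate number as a block over all libraries, it called miR164a, b and f (adjusted p = 0.00720), the 2 of miR319 (0.0476) and the family miR319 (0.0475). With a replicate block within each time, it called the 2 of miR319 (adjusted p = 0.0493), their family (0.00886) and 8 of miR166. The libraries of 7 h alone gave 6 of miR166 that share their counts (adjusted p = 0.0137). The total of miR166 had a log2 fold change of 0.44 with TMM and 0.023 with library totals.

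After 13.5 h miR399a, miR399b and miR399c, which target the PHO2 transcript in phosphate homeostasis, were higher in elevated CO2. They share 1 set of counts and come from the precursors MIR399a, MIR399b and MIR399c. They lay at 19.1 and 9.80 CPM in elevated CO2 against 1.82 and 2.91 CPM in ambient CO2, from counts of 180 and 66 against 24 and 12. Each of these counts is a multiple of 3, the number of precursors. So are the counts at 7 h, at 57 and 54 in ambient and 3 and 39 in elevated CO2. A read thus appears to have entered the row once per precursor, in which case the reads behind the counts are fewer. The log2 fold change was 2.67 ± 0.56 (SE, 6.37-fold, adjusted p = 0.0184 by edgeR), with a 95% interval of 1.49 to 3.86 and both elevated libraries above both ambient ones. The more abundant members of the family, miR399d and miR399j, had values of 0.58 ± 0.48 and 0.71 ± 0.60, and the family total had 0.65 ± 0.46, none of which passed. The call ended when the identical rows were counted once (adjusted p = 0.0597 by edgeR), with library totals (0.223), with limma (0.0886 to 0.178), and without replicate 1 or 2 of ambient CO2 (0.675 and 0.0623) or replicate 1 of elevated CO2 (0.156) at 13.5 h. The log2 fold change was 2.19 without the last of these and 1.82 without both replicate 1 libraries at 13.5 h, which leaves 1 library against 1 (adjusted p = 0.975 by edgeR).

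No other miRNA passed at 13.5 h. Among the values that did not pass, miR827, which targets SPX-domain phosphate transporters, had −1.18 ± 0.82. The 16 miR395 rows that share counts, named here by miR395b, target sulfate assimilation genes and had −0.72 ± 0.48. The others were 0.84 ± 0.47 for miR1878, −0.80 ± 0.58 for miR159f, 0.75 ± 0.49 for miR1863b.2, −0.71 ± 0.54 for miR5504, 0.65 ± 0.49 for miR2878-5p, 0.63 ± 0.40 for miR162a and −0.60 ± 0.41 for miR394. The values of miR1863b.2 and miR394 turned to −0.052 and 0.021 without both replicate 1 libraries, as 1 library against 1.

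The phosphate and sulfate list at 13.5 h had 3 of 5 members higher and 2 lower, with a median of 0.57 and an adjusted p of 0.260 by camera. Its member miR399a passed when adjusted over the list alone, as 1 member, against 0 members over all 201 distinct sets. All 5 copper members lay lower (median −0.57, adjusted p = 0.103 by camera), among them miR397a at −0.71 ± 0.59 and miR528-5p at −0.73 ± 0.61. The leaf development list lay lower in 23 of 34 members, with a median of −0.073, or 0.033 with library totals, and an adjusted p of 0.318. The nitrogen-linked list lay lower in 10 of 14 members (median −0.18, adjusted p = 0.271 by camera). The adjusted p by camera was 0.661 for the auxin, 24-nt and reproductive lists, 0.702 for the SPL-targeting, AP2-targeting and biogenesis lists and 0.833 for the cereal-restricted list. The SPL-targeting list had a median of 0.043 against a mean of −0.23 and a test that pointed down, and the biogenesis list had a mean of −0.038 against a median of 0.14 and a test that pointed up. Leaving out a library, so that 1 library stood against 2, brought lists past the threshold. These were leaf development, auxin (lower) and 24-nt (higher) without replicate 2 of ambient CO2, leaf development and copper (lower) without replicate 1 of elevated CO2, and nitrogen-linked (lower) without replicate 2 of elevated CO2. With an estimated correlation the adjusted p of these lists was 0.495, 0.968 and 0.402 in the same order of libraries, and by fry only the nitrogen-linked list passed (0.0377). Among the mature miRNAs, 5 had an unadjusted p under 0.05, DESeq2 called 3, again miR399a, b and c, and limma called 0. For families edgeR called 0 with 2 at an unadjusted p under 0.05, and DESeq2 and limma called 0.

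**Figure D2:**
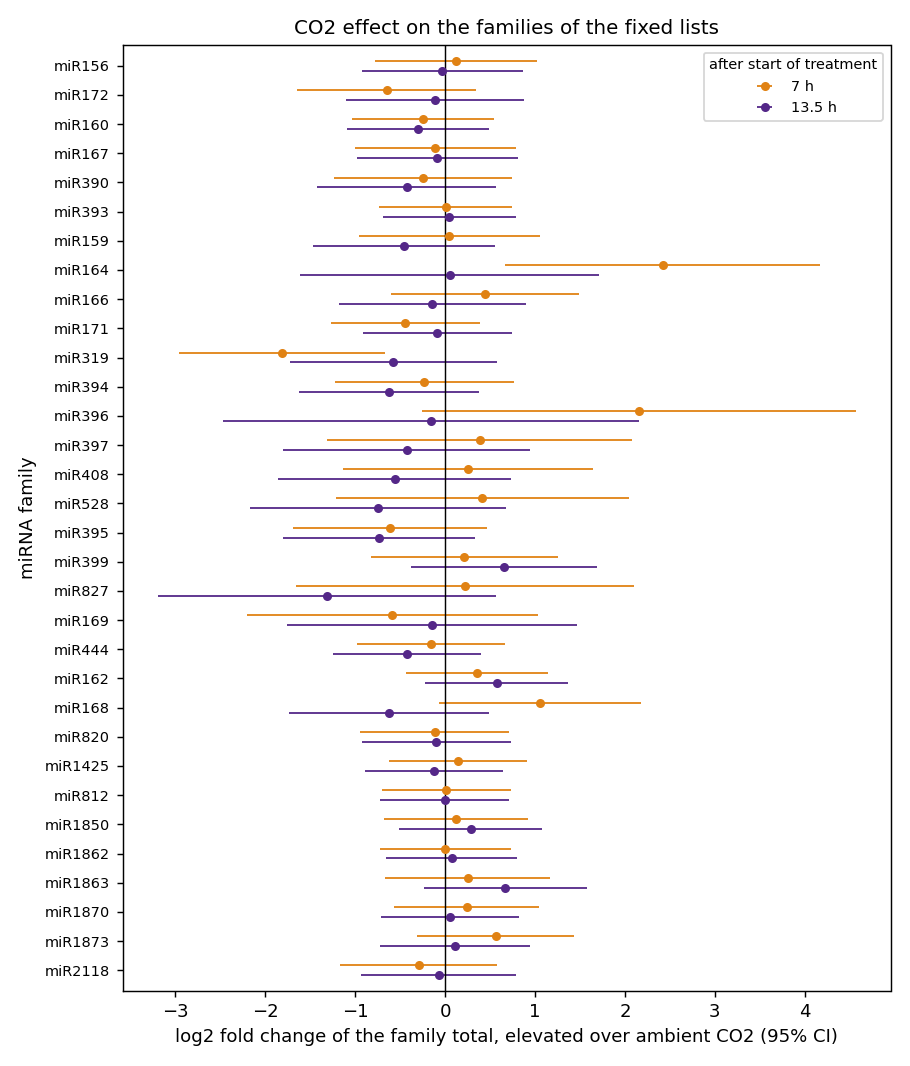
Log2 fold change of the family total, elevated over ambient CO2, for the 32 tested families of the fixed lists at 7 h (orange) and 13.5 h (purple), with 95% confidence intervals from 2 libraries per group as bars. Of the 64 intervals 2 leave out 0, those of miR319 and miR164 at 7 h, and neither family passed after adjustment in this fit, while miR319 passed with a replicate block (adjusted p = 0.0475 by edgeR); the miR164 value rests on 1 library, and many of the small values change sign with library totals as the scaling.

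The CO2 effect did not pass the test of a difference between 7 h and 13.5 h in any mature miRNA or family in the fit without a replicate block. The smallest p belonged to miR399a, b and c, with a difference of 3.17 ± 0.81 (SE, adjusted p = 0.110 by edgeR) between a log2 fold change of −0.50 ± 0.58 at 7 h and that at 13.5 h. Values for miR164a (−2.47 ± 1.09), miR168a-3p (−3.42 ± 1.67), miR396e-5p (−2.51 ± 1.95) and miR396f-5p (−2.51 ± 1.95) include the high replicate 1 of elevated CO2 at 7 h. Without the 3 libraries that lay apart, those of miR168a-3p and miR396e-5p were 0.26 and 0.46. The remaining values were 1.28 ± 0.67 for miR1878, −0.995 ± 0.60 for miR444b.1, 1.21 ± 0.79 for miR319a-3p.2-3p, 0.90 ± 0.68 for miR1880 and −1.50 ± 1.17 for miR827. That of miR168a-5p was −0.56 ± 0.46, and 0.078 with library totals.

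In the copper list the CO2 effect at 13.5 h lay below that at 7 h, relative to other miRNAs. All 5 members, from 3 families with low counts, were lower, among them miR528-3p at −1.08 ± 0.85 and miR397a at −1.03 ± 0.92. The median of the copper list was −1.02 and its adjusted p was 0.0101 by camera and 0.944 by fry, or an adjusted p of 0.894 with an estimated correlation. The leaf development list also lay lower, with 27 of 34 members lower, a median of −0.32 and an adjusted p of 0.0101 by camera and 0.944 by fry, or an adjusted p of 0.894 with an estimated correlation. These members come from 7 families, most of them from miR166 and miR396, so their number does not show a shift of many families. The totals of miR171 (0.36) and miR319 (1.24) were higher. With library totals the median of the copper list was −0.55 and that of the leaf development list was 0.22. No member of either list passed, over all miRNAs or adjusted over the list alone. Both calls ended without replicate 1 of ambient CO2 at 7 h (adjusted p = 0.759 for copper and 0.180 for leaf development by camera), without replicate 1 of ambient CO2 at 13.5 h (0.118 and 0.801) and without replicate 2 of elevated CO2 at 13.5 h (0.512 and 0.327). The leaf development call also ended without replicate 1 of elevated CO2 at 7 h (0.120) and without both replicate 1 libraries at 13.5 h (0.393), and the copper call without replicate 2 of elevated CO2 at 7 h (0.371) or of ambient CO2 at 13.5 h (0.0704). Without replicate 1 of elevated CO2 at 13.5 h the nitrogen-linked list passed as higher (adjusted p = 0.0357 by camera and 0.0179 by fry, or an adjusted p of 0.603 with an estimated correlation). The other 9 lists had an adjusted p of 0.493 or above with all libraries, and in the phosphate and sulfate list miR399a passed when adjusted over the list alone. The median and the mean differed in sign in that list (−0.013 and 0.43), in the SPL-targeting list (−0.083 and 0.045), the auxin list (−0.030 and 0.028) and the cereal-restricted list (0.073 and −0.011), and the test had the sign of the mean. Of the miRNAs, 0 passed by edgeR, DESeq2 and limma, with 4 at an unadjusted p under 0.05; of the families, 0 passed by each tool, with 2 at an unadjusted p under 0.05. Without replicate 2 of elevated CO2 at 7 h edgeR called 4 miRNAs (miR164a, b and f and miR168a-3p) and 1 family (miR164). Without replicate 2 of elevated CO2 at 13.5 h it called 3, miR399a, b and c (adjusted p = 0.0467), which also passed with a replicate block over all libraries (0.0292) or within time (0.00625). The block within time also called 6 of miR166 that share their counts (−0.66 ± 0.14, adjusted p = 0.000830 by edgeR). The total of miR166 had a difference of −0.59 with TMM and −0.027 with library totals.

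Over both times, with 4 libraries against 4, no mature miRNA or family passed the test between CO2 levels. The lowest p belonged to miR319a-3p.2-3p, at 10.7 CPM ± 6.74 (SD, n = 4) in elevated and 32.5 CPM ± 30.3 (SD, n = 4) in ambient CO2. Its log2 fold change was −1.19 ± 0.41 (SE, adjusted p = 0.857 by edgeR). That of miR162a, which targets the miRNA-processing enzyme DCL1, was 0.57 ± 0.25. With TMM, all 4 elevated libraries (260 to 482 CPM) lay above the 4 ambient ones (206 to 249 CPM) in miR162a. With library totals this separation was lost, since replicate 2 of elevated CO2 at 7 h fell below both ambient libraries of that time. The miR162 family total then moved from 0.46 to 0.26 over both times and from 0.36 to −0.063 at 7 h. Values of −0.64 ± 0.31 for miR395b, −0.71 ± 0.37 for miR5504, 0.59 ± 0.32 for miR1863b.2, 0.77 ± 0.42 for miR399j and 0.42 ± 0.25 for miR1876 did not pass. Nor did those of 1.33 ± 0.78 for miR164a, 0.41 ± 0.26 for miR2877 and 0.45 ± 0.32 for miR2878-5p. Without replicate 1 of elevated CO2 at 7 h those of miR164a, miR399j and miR1876 were 0.27, 0.30 and 0.19. The values of miR399j and miR2878-5p were −0.047 and −0.041 without the 3 libraries that lay apart.

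The nitrogen-linked list lay lower in elevated CO2 over both times, with 12 of 14 members lower, among them miR169i-3p at −0.49 ± 0.32 and miR444a-3p.2 at −0.32 ± 0.24. Its median was −0.32 and its adjusted p was 0.0371 by camera and 0.807 by fry, or an adjusted p of 0.676 with an estimated correlation. No member of any list passed when adjusted over the list alone. The call ended without replicate 1 or 2 of ambient CO2 at 7 h (adjusted p = 0.0566 and 0.0979 by camera), without replicate 2 of elevated CO2 at 7 h (0.197), and without replicate 1 of ambient or elevated CO2 at 13.5 h (0.137 and 0.360). Without the 3 libraries that lay apart it was 0.834. Its adjusted p without replicate 2 of elevated CO2 at 13.5 h was 0.00100 by camera and 0.0228 by fry, or an adjusted p of 0.147 with an estimated correlation. The biogenesis and reproductive lists then also passed by fry (0.0217 and 0.00871), but not by camera. The other 10 lists had an adjusted p of 0.265 or above by camera with all libraries. The leaf development list passed as higher without replicate 1 of ambient CO2 at 13.5 h (adjusted p = 0.0277 by camera, or an adjusted p of 0.693 with an estimated correlation). The auxin list passed as lower and the 24-nt list as higher without replicate 2 (0.0174 and 0.0351 by camera, or an adjusted p of 0.481 and 0.513 with an estimated correlation). Of the miRNAs 0 passed by edgeR, DESeq2 and limma, with 3 at an unadjusted p under 0.05; of the families 0 passed by each tool, with 2 at an unadjusted p under 0.05. The median half-width of the 95% intervals was 0.69 on the log2 scale over both times, against 1.07 at 7 h and 1.04 at 13.5 h.

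Between 7 h and 13.5 h, over both CO2 levels, no mature miRNA passed in the fit without a replicate block. Lists of copper, nitrogen-linked and reproductive miRNAs passed by camera at the preset correlation, but 0 lists passed with an estimated correlation or by fry. The copper list lay higher at 13.5 h than at 7 h, with 4 of 5 members higher and a median of 0.98, or 0.55 with library totals. Its adjusted p was 0.00189 by camera and 0.301 by fry, or an adjusted p of 0.534 with an estimated correlation. Its member miR528-5p, which targets copper proteins such as ascorbate oxidase, had 9.33 CPM ± 4.38 (SD, n = 4) at 13.5 h against 1.97 ± 0.868 (SD, n = 4) at 7 h, with all 4 libraries at 13.5 h above those at 7 h. Its log2 fold change was 2.28 ± 0.53 (SE, adjusted p = 0.102 by edgeR), and it was the 1 copper member that passed when adjusted over the list alone. The laccase-targeting miR397b and miR397a had 1.33 ± 0.56 and 0.98 ± 0.45, and miR408-3p, which targets plantacyanin, had 0.94 ± 0.41.

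The nitrogen-linked list lay lower at 13.5 h, with 12 of 14 members lower and a median of −0.43, or −0.74 with library totals, among them miR169b at −1.47 ± 0.49 and miR444f at −1.23 ± 0.51. Its adjusted p was 0.00750 by camera and 0.301 by fry, or an adjusted p of 0.534 with an estimated correlation. The reproductive list lay lower as well, with all 3 miR2118 members lower (−0.86 ± 0.30 for miR2118c) and 2 of them passing when adjusted over the list alone. Its median was −0.80 and its adjusted p was 0.00750 by camera and 0.0776 by fry, or an adjusted p of 0.402 with an estimated correlation. The copper call ended without both replicate 1 libraries at 13.5 h (adjusted p = 0.0716 by camera) and without the 3 libraries that lay apart (0.0522). The nitrogen-linked call ended without replicate 1 of elevated CO2 at 13.5 h (0.0918) and without both replicate 1 libraries (0.153). The leaf development list had 19 members higher and 15 lower, with 1 passing when adjusted over the list alone (miR319a-3p.2-3p). Its median was 0.13, or −0.33 with library totals, while its test pointed down (adjusted p = 0.875 by camera). Without replicate 1 of ambient CO2 at 13.5 h it passed as lower and the 24-nt list as higher (adjusted p = 0.0465 each by camera, or an adjusted p of 0.493 each with an estimated correlation). The nitrogen-linked and reproductive lists passed by fry without replicate 2 of elevated CO2 at 13.5 h (0.0211 and 0.00472), but with an estimated correlation they had an adjusted p of 0.198 and 0.215. The adjusted p by camera was 0.213 for the AP2-targeting, 0.414 for the phosphate and sulfate, 0.517 for the SPL-targeting, 0.715 for the 24-nt, 0.875 for the cereal-restricted and 0.996 for the auxin and biogenesis lists.

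The smallest p between the times belonged to miR319a-3p.2-3p and miR319b, with 8.07 CPM ± 3.28 (SD, n = 4) at 13.5 h against 35.2 ± 28.0 (SD, n = 4) at 7 h. Their log2 fold change was −1.96 ± 0.42 (SE, adjusted p = 0.0684 by edgeR). The next among well-counted miRNAs were miR159f at −1.56 ± 0.40 and miR159a.2 at −1.23 ± 0.35, each with its 4 libraries at 13.5 h below those at 7 h. Further values that did not pass were 0.83 ± 0.26 for miR2880, −1.03 ± 0.37 for miR444d.3, 0.73 ± 0.27 for miR166g-3p and 0.64 ± 0.24 for miR166i-3p. They were −0.76 ± 0.28 for miR2118e, 0.68 ± 0.25 for miR1862a and 0.68 ± 0.26 for miR2877. The count of 0 miRNAs by edgeR stood beside 34 at an unadjusted p under 0.05, of which 17 were higher and 17 lower, with 15.7 of 313 rows expected by chance. These 34 rows held 25 distinct sets of counts. With library totals 28 had an unadjusted p under 0.05, and 1 of them was higher. DESeq2 called 4 (miR319a-3p.2-3p, miR319b, miR159f and miR528-5p) and limma 0. For families edgeR called 0 with 9 at an unadjusted p under 0.05, DESeq2 1 (miR319) and limma 0. With a replicate block over all libraries edgeR called miR159f (adjusted p = 0.0421), the 2 of miR319 (0.0117) and the family miR319 (0.0263). Without replicate 2 of elevated CO2 at 13.5 h it called 20 miRNAs, and without replicate 1 of ambient or of elevated CO2 at 7 h it called the 2 of miR319. Without replicate 1 of elevated CO2 at 7 h it also called 1 family, miR319, and without the 3 libraries that lay apart, which leaves 2 libraries at 13.5 h against 3 at 7 h, it called 7 miRNAs, the 2 of miR319 among them (−1.88 ± 0.38, adjusted p = 0.0318).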

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

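The 2 alternatives that leave out several libraries and the fit with identical rows kept once inside the replicate block were chosen after seeing the data. Counts of 0 to 3 can change with 1 row, and the cause of a change was not tested unless stated. DESeq2 called 4 miRNAs and 2 families for CO2 at 7 h, and 4 miRNAs and 1 family for time. The libraries of 7 h alone gave 6 miRNAs. For CO2 at 13.5 h the count of 3 miRNAs became 0 with library totals, with identical rows kept once, and with limma on log2(RPM + 1), on log2(RPM + 0.1) and on the authors' normalized log2 values. The filter at 10 CPM removed these 3 rows, at a TMM-scaled mean of 6.41 CPM, before the test, so it could not test them again. Leaving out both 13.5 h libraries numbered 1 leaves 1 library against 1 at 13.5 h, with the spread taken from 7 h. Its calls of lists for CO2 at 13.5 h and for the difference are therefore not taken as support. For CO2 over both times camera then called 0 lists. With the 3 libraries highest on the first component left out, 3 of the 4 groups keep 1 library, so for CO2 at each time and the difference the spread comes from the pair of ambient CO2 at 7 h alone, the pair with the fewest 2-fold differences. Its calls for these comparisons are therefore not taken as support. In this setting edgeR called 8 miRNAs for CO2 at 7 h, 0 for CO2 at 13.5 h, 6 for the difference and 7 for time, and camera called 3 lists for CO2 at 13.5 h, 4 for the difference and 0 for CO2 over both times. The estimated correlation called 0 lists in the difference, in CO2 over both times and in time.

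With each library left out in turn, a group of 2 keeps 1 library, which is assumed to vary like the other groups. The counts of miRNAs then ran from 0 to 5 for CO2 at 7 h, from 0 to 3 for CO2 at 13.5 h, from 0 to 4 for the difference and from 0 to 20 for time. Those of families ran from 0 to 2 for CO2 at 7 h, from 0 to 1 for the difference and from 0 to 1 for time. Those of lists ran from 0 to 2 for CO2 at 7 h (2 without replicate 2 of ambient CO2 at 7 h), from 0 to 3 for CO2 at 13.5 h (3 without replicate 2 of ambient CO2 at that time, 2 and 1 without replicate 1 and 2 of elevated CO2), from 0 to 3 for the difference, from 0 to 3 for CO2 over both times and from 2 to 5 for time (5 without replicate 1 of ambient CO2 at 13.5 h). The counts for CO2 over both times (miRNAs and families) and for CO2 at 13.5 h (families) were 0 under all alternatives run.

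The replicate numbers were not taken to pair the libraries, since the labels do not say that a number marks a shared experiment. Deviations from the group means, over 93 miRNAs, correlated at −0.06 between the groups at 7 h and at 0.51 between those at 13.5 h. Across times they correlated at −0.40, −0.57, 0.41 and 0.36. By these deviations 4 of 8 libraries correlated best with a library of their own number. In a group of 2, however, 1 deviation is the negative of the other. The 8 outcomes are thus mirrored pairs and cannot settle whether a number marks a shared experiment. With the number as a replicate block over all libraries, edgeR called 5 miRNAs and 1 family for CO2 at 7 h, 3 miRNAs for the difference (miR399a, b and c), and 3 miRNAs and 1 family for time. With a replicate block within each time it called 10 miRNAs and 1 family for CO2 at 7 h and 10 miRNAs for the difference, which were miR399a, b and c, miR1428e-3p and 6 of miR166. The replicate block with identical rows kept once gave 1 miRNA for CO2 at 13.5 h. The blocks over all libraries and within time left the count of 3 for CO2 at 13.5 h, and the block over all libraries left the counts of lists, within 1.5 times.

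For the 50 named values, 1065 of 1079 alternatives were not reversed, 23 passed the threshold where the main test did not, and 10 of the miR399a row lost it. The value of miR166g-3p for time was 0 on the authors' normalized log2 scale. Reversed were miR168a-3p for CO2 at 7 h (from −0.082 without replicate 1 to 3.17 without replicate 2 of elevated CO2 at 7 h, and −0.11 without the 3 libraries), miR1863b.2 (−0.052) and miR394 (0.021) for CO2 at 13.5 h, both without the libraries numbered 1 at 13.5 h and without the 3, and miR168a-5p for the difference (0.078 with library totals, 0.050 on both log2 RPM scales). Without the 3 libraries, miR168a-3p (0.26), miR396e-5p (0.46) and miR396f-5p (0.46) reversed for the difference, and miR399j (−0.047) and miR2878-5p (−0.041) for CO2 over both times. Depth limits the shallowest library most, where the miR399a row had a count of 3 and miR817 had 16.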

Other observations

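The tests of depth and of a shared experiment below, and that of identical rows for miR399a, were chosen after the result was seen. The arms of miR168a, whose 5p arm guides the cleavage of AGO1 transcripts, did not keep 1 ratio. The 3p arm was at 2.69 times the 5p arm in replicate 1 of elevated CO2 at 7 h and at 1.11 times in replicate 1 of ambient CO2 at 13.5 h, against 0.279 to 0.443 in the other 6 libraries. The 5p arm itself lay between 553 and 757 CPM in all 8. Both of these libraries also had high miR396e-5p, while replicate 1 of elevated CO2 at 13.5 h had high miR396e-5p with an arm ratio of 0.420.

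The estimated CO2 effects at the 2 times, which share no library, showed no clear correlation across miRNAs. Over 201 distinct miRNAs, which are not independent replicates, the log2 fold changes at 7 h and 13.5 h had a Pearson's r of −0.01 and a Spearman's rho of 0.07, and 52.7% had the same sign. The median SE over the 313 rows was 0.51 at 7 h and 0.49 at 13.5 h. Noise of this size can hide a shared effect, so these values cannot show that the true effects are unrelated. A feature singled out after its values were seen is miR1428e-3p, at −2.09 ± 0.89 (SE) for CO2 at 7 h and 1.99 ± 0.82 at 13.5 h, a difference of 4.08 ± 1.21 (adjusted p = 0.276 by edgeR) at a mean of 1.69 CPM. Another is miR5077, at 268 and 2087 CPM in replicates 1 and 2 of elevated CO2 at 13.5 h and at 849 and 2449 CPM in those of ambient CO2.

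Libraries numbered 1 at 13.5 h lay apart at both CO2 levels, with miR396e-5p higher than in number 2 by 2.40 (ambient) and 1.66 (elevated) on the log2 scale. Sequencing depth cannot be told apart from other differences. The 2 libraries are the deepest, and the deeper library had the higher miR396e-5p in 3 of the 4 groups; in elevated CO2 at 7 h the shallower one was higher by 3.12 on the log2 scale, but that is 1 library of another group. Nor can an experiment shared by the 4 libraries of a number, since number 1 was lower in ambient CO2 at 7 h (−0.66) but higher in the other 3 groups. A difference in leaf age was not tested.

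The higher miR399a, b and c in elevated CO2 at 13.5 h rest on 1 set of reads counted in 3 rows. Keeping the rows once does not undo a repeated count within the row. Counted once, the log2 fold change was 2.65 ± 0.50 (SE) in place of 2.67 ± 0.56, and the adjusted p was 0.0597, because the 3 identical p-values no longer lift each other's rank and the unadjusted p rose from 0.000176 to 0.000297 in the refit; the adjusted p ran from 0.000356 to 0.975 over the alternatives. The log2 fold change was 2.62 or above under the other scalings, and 2.19 or above without any 1 of the 4 libraries at 13.5 h. The call itself ended with library totals and without 3 of these libraries. The row stood out in these same libraries. The values therefore show only that no 1 scaling or library makes up the fold, and they are not evidence for an effect of CO2. At 13.5 h miR827, which is also linked to phosphate, had −1.18 ± 0.82. The phosphate and sulfate list had 3 members higher and 2 lower (adjusted p = 0.260 by camera). An effect of CO2 on miR399a, b and c late in the light period is a hypothesis that these data leave open. The family total did not pass, and of the alternatives run the difference from 7 h passed only with a replicate block (adjusted p = 0.0292 over all libraries and 0.00625 within time) and without replicate 2 of elevated CO2 at 13.5 h (0.0467), not in the fit without a block (0.110) or with identical rows counted once (0.217).

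Splits of the 8 libraries into 4 and 4 were refitted, 35 for each comparison. They say nothing about chance for counts of 0, which all 35 splits must reach: the 0 miRNAs of the CO2 comparison (highest other 16) and of the time comparison (highest other 27), and the 0 families of both (highest other 5 and 1). Chance could not be excluded for the 34 miRNAs with an unadjusted p under 0.05 between times, since 6 of the 35 splits, the real one among them, gave at least as many, with 79 as the highest other. The split with 27 miRNAs set the 3 libraries that lie apart and replicate 2 of ambient CO2 at 13.5 h against the rest. That split also sets most libraries of 13.5 h against most of 7 h, and the split with 16 miRNAs did not set those 3 libraries apart. Whether such counts exceed chance was not tested, so they cannot show a structure of the samples other than CO2 or time.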
